A study of Drosophila melanogaster with 2 samples.

How the data were processed

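Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of mixed sex, 0 to 24 h old, from a transgenic line that carries gem with GFP fused to its C-terminus. Gem (gemini) belongs to the CP2 and Grainyhead family of transcription factors. Per the labels, an antibody against GFP was used for the precipitation and chromatin was fragmented by sonication, with a size range of 200 to 800 bp. The series had 1 group with 2 samples, which the labels number as biological replicates 1 and 4. No second condition was present, so every comparison was made within this group or against the genome.

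Peak lists of 4 kinds were read. Per the accompanying listings deposited with the samples, replicate 1 and replicate 4 each had peaks called on their own alignments with a control alignment as further input. A pooled list was called on both replicates together. A list thresholded by the irreproducible discovery rate (IDR), a measure of how well peak ranks are kept between replicates, was made from these lists. All were on assembly dm6. The aligner, the peak caller, the IDR threshold and their versions were not given in the sources used here. Each peak had a signal value, the peak's own value as the authors' caller gave it, and a −log10 q-value, also as deposited. The scaling of the signal is not stated, so signal values were used to describe and rank peaks within a list and not to compare levels between lists. The −log10 q-value was at its highest value in 88.0% of the IDR peaks, so peaks were ranked by signal. Read depth per sample is unknown from these lists, and coverage tracks and control reads were not used here.

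Coordinates of dm6 were read with the release 6 assembly of the same arm lengths, its sequence from RefSeq and gene models from Ensembl release 115 (BDGP 6.54). No peak ended beyond its arm. Analyses covered arms X, 2L, 2R, 3L, 3R and 4, which held every listed peak. Annotated transposable elements were left out of the gene models, which left 18164 genes with 23581 distinct transcription start sites (TSSs). Coordinates below are 1-based. A promoter peak had its summit within 500 bp of a TSS and any other peak was distal.

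Peaks of the replicates were matched when their summits lay within 100 bp. Replicate overlap was computed over the 11045 strongest peaks of each replicate, 11045 being the length of the IDR list, against 100 random placements on the same arms outside gaps (one-sided permutation test). The promoter share was tested with 1000 such placements (two-sided). Peaks per arm were tested with an exact binomial test against arm length. Signal at promoter and distal peaks was compared with 100000 permutations of the labels. Motifs were searched on both strands within 50 bp of summits and in windows of the same width centred 500 bp to either side, with Fisher's exact test. All 8-mers were tested the same way with the hypergeometric form. Each of the 25 gene lists was compared with all other protein-coding genes by Fisher's exact test. P-values were adjusted by the Benjamini-Hochberg method within the 6 arms, the 12 fixed motifs, the 8-mers and the 25 lists, with a threshold of 0.05. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. These tests take peaks, windows or genes as units. They describe the lists of this group, with only 2 replicates behind them, and neighbouring peaks are not fully independent. 

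The gene lists, the motifs, the tests and the rule for naming genes were fixed before the data were examined. The rule takes gem and its paralogue grh, the genes with a TSS nearest to the 25 strongest IDR peaks that were also among the 11045 strongest of both replicates, and up to 4 members per gene list with the highest signal at a promoter peak. Where fewer than 4 members had such a peak, up to 2 members without one could be named. Members named outside this rule are said to be so. Symbols that matched no single annotated gene were left out of the lists: 1 each in the trachea, germline, testis, signalling, Polycomb and insulator lists.

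Alternatives changed the matching distance, the number and ranking of peaks, the TSS window and TSS set, the motif window and background, the 8-mer length, the gene background, the peak set and the replicate used. Random positions matched on GC content, and 8-mers against dinucleotide shuffles, were added after the data were seen. The functions were tested on simulated data. With a planted overlap of 80.4% between replicates, 80.7% was recovered. A planted 8-mer ranked first of 32896, and 0 8-mers were called with nothing planted. In 200 simulations a ribosomal protein list raised to a share like the observed one was called in 100% of them, and 0.375% of unchanged lists were called. The simulated 8-mer windows lay at random genome positions, without the low GC content of the summits. Simulated genes were drawn without regard to their number of TSSs. These runs therefore check the functions and do not give the rate of false calls in the observed data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.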

Results

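Binding of GFP-tagged gem was mapped in whole 0 to 24 h embryos by ChIP-seq, with 2 biological replicates numbered 1 and 4. Gem is the fly member of the CP2 branch of the family whose other branch is Grainyhead (grh), the regulator of epidermal barrier genes. The lists of replicate 1, replicate 4 and the pooled replicates held 30000 peaks each. The IDR list held 11045 peaks with a median width of 330 bp, and it was made up of exactly the 11045 pooled peaks of highest signal. Its signal values ran from 187 to 17817.8 with a median of 432. Read depth is unknown from these lists.

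Most of the strong sites were recovered in both replicates. Of the 11045 strongest peaks of replicate 1, 8844 (80.1%, 95% interval 79.3 to 80.8) had a summit within 100 bp of 1 of the 11045 strongest of replicate 4. Random placement gave a mean of 1.69% and at most 1.90% (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Among the 1000 strongest peaks of each replicate the share was 86.5%. Across the 10416 IDR peaks matched in both replicates, signal correlated with a Spearman coefficient of 0.872 (bootstrap 95% interval 0.865 to 0.879) and a Pearson coefficient of 0.906 on the log10 scale. The IDR list was made from these same 2 replicates, so part of this agreement may follow from how its peaks were chosen. Of its 11045 peaks, 8788 (79.6%) had a match within 100 bp among the 11045 strongest of both replicates. The coefficients are across peaks, which are not independent replicates. They were 0.921 for promoter peaks and 0.851 for distal peaks (Spearman).

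The highest IDR signal, 17817.8, was on arm 3L at 19590383 to 19590883, with the summit in intergenic sequence 90 bp from the TSS of CG14100. It ranked first in both replicates, with signal 13253 in replicate 1 and 4604 in replicate 4. The next, at 14808, was on 2R at 15217559 to 15218047, intergenic and 143 bp from mRpL41, a protein of the mitochondrial large ribosomal subunit. A peak of 13417 on 3R at 15229305 to 15229773 lay 124 bp from Art3, an arginine methyltransferase gene, and 133 bp from mRpS10 of the mitochondrial small subunit. Ugalt, a UDP-galactose transporter gene, had a peak of 12596 at 40 bp on X at 2703638 to 2704190, and PNPase, for mitochondrial RNA processing, a peak of 10776 in its 5' UTR. Chromatin genes in this set included ph-p, a Polycomb group gene with an intronic peak of 11614 at 476 bp, Chro (chromator), with a peak of 11143 in its 5' UTR at 78 bp, and Trl (GAGA factor), with an intronic peak of 11048 at 1531 bp. A peak of 14063 on 2L at 480464 to 481339, in an intron of another gene, was 1390 bp from the TSS of cbt, which encodes a zinc finger transcription factor. Other genes nearest to the top 25 peaks included px, Lk6, msi, HmgZ and CenG1A, with signals from 9113 to 12127. Of the 25 peaks, 17 were promoter peaks, and all 25 ranked no lower than 27 in either replicate.

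Both genes of the family carried peaks themselves. The gem gene (2R, 10124293 to 10137472, plus strand) had 3 IDR peaks in the gene or within 1000 bp of it. The strongest, with signal 843, was intergenic at 10123583 to 10123889, 563 bp from a TSS, with 559 in replicate 1 and 284 in replicate 4. A weaker peak of 220 lay in the 5' UTR at 10124160 to 10124563, 69 bp from a TSS. The grh gene (2R, 17801132 to 17842820, plus strand) had 5 by the same measure. Its strongest, 2998, was intronic at 17804685 to 17805146 and 2061 bp from the nearest TSS, and ranked 398 of the 11045 IDR peaks. A second grh peak, 1025, lay in a non-coding exon 139 bp from a TSS at 17801151 to 17801516.

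Promoters and introns held most sites, and coding sequence held almost none. Summits within 500 bp of a TSS numbered 3361 of 11045 (30.4%, interval 29.6 to 31.3), against a mean of 13.5% for random placements, 2.25-fold higher (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Introns outside these windows held 4965 summits (45.0%, random mean 39.6%) and intergenic sequence 2422 (21.9%, random mean 27.2%). Coding exons held 16 summits (0.145%, random mean 13.7%) and 3' UTRs 111 (1.00%, random mean 4.45%). Positions matched to the summits on arm and on GC content within 50 bp, a background chosen after the data were seen, fell in coding exons in 2.38%, at promoters in 13.7%, in introns in 44.3%, in intergenic sequence in 30.1% and in 3' UTRs in 8.17%, so that the intron share was 1.01 times that of matched positions. Distal summits lay a median of 3200.5 bp from the nearest TSS.

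**Figure D1:**
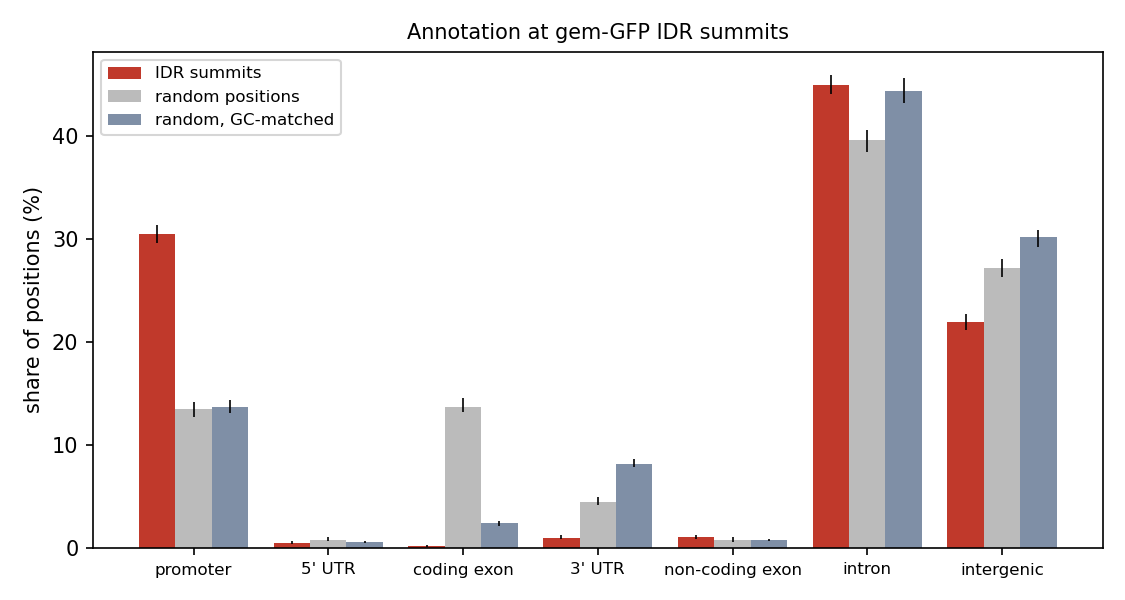
Share of positions (%) by annotation, with promoter meaning within 500 bp of a TSS and taking precedence, for 11045 IDR summits (red, exact 95% intervals), 50 random placements (light grey, mean with range) and 20 draws of GC-matched positions (blue-grey, mean with range). Promoter summits stood at 30.4% against 13.5% for random placement, and coding exon summits at 0.145% against 13.7%.

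Promoter summits were mostly upstream of the TSS. Of the 3361, 2739 (81.5%, interval 80.1 to 82.8) lay upstream of the nearest TSS, and the fullest 50-bp bin was 150 to 100 bp upstream, with 619 summits (18.4%). The 100 bp immediately downstream of the TSS held 131 and 98 summits in its 2 bins.

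**Figure D2:**
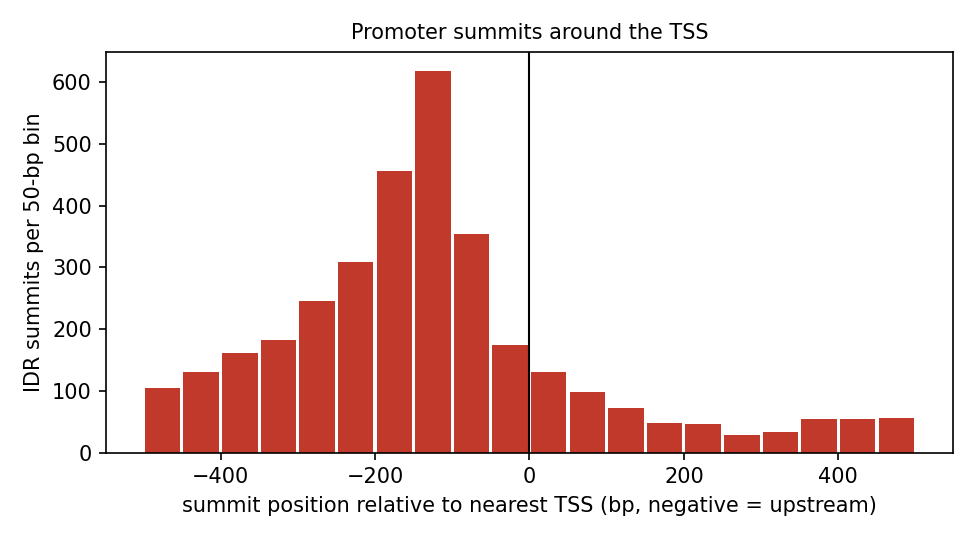
Number of promoter IDR summits per 50-bp bin (vertical axis) by position relative to the nearest TSS in bp (horizontal axis, negative values upstream; 3361 summits). The highest bar, 619 summits, covers 150 to 100 bp upstream.

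Peaks at TSSs were counted for each class of gene, without a test between classes. Of 13945 protein-coding genes, 3432 (24.6%, interval 23.9 to 25.3) had an IDR summit within 500 bp of a TSS. The shares were 53 of 290 tRNA genes (18.3%, interval 14 to 23.2), 408 of 3261 non-coding RNA genes (12.5%, 11.4 to 13.7), 4 of 32 snRNA genes (12.5%, 3.51 to 29.0), 20 of 269 snoRNA genes (7.43%, 4.60 to 11.2) and 12 of 268 pseudogenes (4.48%, 2.33 to 7.69). No peak was found at 99 rRNA genes, which allows a share of up to 3.66% if each gene counts as a separate unit. Whether a peak could be called at each of these genes was not measured, so absence of binding is not shown.

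Peak counts departed from arm length on all 6 arms, with more peaks on X, 2L and 3L and fewer on 2R, 3R and the small chromosome 4. How much of each arm could yield a called peak was not measured. These ratios therefore describe counts per length and do not by themselves show a preference of binding. X held 2209 peaks, 1.14-fold its expectation (exact binomial test, adjusted p = 1.19e-10), or 94.1 per Mb. Arm 2R held 1701, a ratio of 0.814 (exact binomial, adjusted p = 2.5e-21), and chromosome 4 held 65, a ratio of 0.591 (exact binomial, adjusted p = 6.46e-06). Ratios for 2L, 3L and 3R were 1.07, 1.09 and 0.935 (exact binomial, adjusted p = 5.89e-04, 6.46e-06 and 1.26e-04). The 3R call was lost in the stronger 5522 peaks (0.961, exact binomial, adjusted p = 0.108), and the ratio of chromosome 4 was 0.364 there. Promoter peaks counted against the TSSs of each arm passed the threshold on 2R alone, at 616 peaks and a ratio of 0.888 (exact binomial, adjusted p = 0.00491). Without replicate 1, 3L also passed, at 793 peaks and a ratio of 1.08 (exact binomial, adjusted p = 0.0487). Over the whole IDR list the promoter ratios for X and chromosome 4 were 1.05 and 1.5, with adjusted p = 0.291 and 0.0528 by the exact binomial test. In the stronger 5522 peaks the direction for chromosome 4 turned, at 10 promoter peaks and a ratio of 0.627 (exact binomial, adjusted p = 0.385).

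Promoter peaks were stronger than distal peaks. The median signal was 585 over 3361 promoter peaks and 394 over 7684 distal peaks, a 1.49-fold ratio. The difference of medians was 0.17 on the log10 scale (bootstrap 95% interval 0.15 to 0.20; permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). It was also present in each replicate's own values, at 1.47-fold in replicate 1 and 1.56-fold in replicate 4.

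Among the 25 gene lists, 6 had promoter peaks more often than other protein-coding genes and 3 less often. Genes with such a peak are called bound here. No sample without the tagged protein was present, so signal that does not depend on gem was not measured. Ribosomal protein genes stood out: 63 of 92 (68.5%, interval 58.0 to 77.8) had a promoter peak, against 24.3% of other genes, an odds ratio of 6.76 (Fisher's exact test, adjusted p = 9.20e-18). The odds ratio was 11.1 without replicate 1 and 3.38 in the stronger 5522 IDR peaks. RpL34b on 3R had a peak of signal 3741 at 9401134 to 9401602, 165 bp from its TSS, RpS20 one of 2353 at 139 bp, RpS27 one of 1772 and RpL32 one of 1673. These 4 were named for the highest signal in the list. In the stronger 5522 IDR peaks, 38 of the 92 genes had a promoter peak. Of the mitochondrial ribosomal protein genes, 30 of 73 (41.1%) had a promoter peak (odds ratio 2.15, Fisher's exact adjusted p = 0.0198). Given the nearest TSS at any distance, this direction turned (odds ratio 0.515, Fisher's exact adjusted p = 0.0674), and among genes with a pooled peak at a TSS the call was lost (odds ratio 3.20, Fisher's exact adjusted p = 0.113). The bound genes were led by mRpL41, mRpS10, mRpS23 (9113 on 2L, 388 bp from the TSS and shared with CenG1A) and mRpL23 (7892). Proteasome genes did not pass the threshold, with 10 of 48 (20.8%; odds ratio 0.806, Fisher's exact adjusted p = 0.743), of which Rpn3 had the strongest peak at 2257, followed by Rpn11, Rpn5 and Rpn13.

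Epithelial junction, cell cycle and chromatin architecture genes were also more often bound. Of the septate junction genes, which seal epithelia, 12 of 25 had a promoter peak (48.0%, odds ratio 2.83, Fisher's exact adjusted p = 0.0426), led by bark (2700 in an intron on 2L, 3789309 to 3789709), Atpalpha (1817), Gli (1573) and M6 (1079). Of the adherens junction and polarity genes, 8 of 15 had one (53.3%, odds ratio 3.51, Fisher's exact adjusted p = 0.0451), with sqh (myosin regulatory light chain, 1940), par-6 (1753), pyd (1665) and shg (E-cadherin, 959) the strongest. The cell cycle list had 13 of 28 (46.4%, odds ratio 2.66, Fisher's exact adjusted p = 0.0451), with Dp at 2210, Cdk1 at 1611, Mcm2 at 1207 and aurB at 1085. Insulator and architectural proteins had 9 of 16 (56.3%, odds ratio 3.95, Fisher's exact adjusted p = 0.0333), with Chro at 11143, Cp190 at 5693, pzg at 2905 and M1BP at 2828. Genes with several TSSs have more chances of a promoter peak. Against 10000 random lists matched on the number of TSSs, these 4 lists no longer passed (permutation, adjusted p from 0.0786 to 0.482), while both ribosomal lists did. The 4 calls were also lost with TSSs within 1000 bp, among genes with a pooled peak at a TSS, and with each peak given to the nearest TSS. Without replicate 1 the septate junction call was lost (odds ratio 2.46, Fisher's exact adjusted p = 0.0579), and without replicate 4 the cell cycle call (2.32, Fisher's exact adjusted p = 0.122). The insulator odds ratio was 7.99 without replicate 1 (Fisher's exact adjusted p = 8.25e-04). In the stronger 5522 peaks the calls of septate junction (1.5), cell cycle (2.25) and insulator genes (3.70) were lost (Fisher's exact adjusted p from 0.0613 to 0.591) and that of adherens junction was kept (5.44). With TSSs within 250 bp the septate junction, adherens junction and cell cycle calls were lost (Fisher's exact adjusted p from 0.056 to 0.830).

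Promoters of sensory, testis and early patterning genes were rarely bound. Chemoreceptor and odorant binding protein genes had peaks in 5 of 230 (2.17%, interval 0.710 to 5.00; odds ratio 0.0667, Fisher's exact adjusted p = 3.82e-20). The strongest was 631 at Obp83g, followed by Obp99b at 487, Obp83cd at 281 and Gr77a at 269, with Ir67c at 225, named after its value was seen, the weakest. None of 21 testis-specific genes, such as betaTub85D and dj, had one, which allows a share of up to 16.1% (Fisher's exact adjusted p = 0.0255). Of 24 segmentation genes, 1 had a promoter peak, hry (hairy), with a signal of 209 in its 5' UTR (4.17%, odds ratio 0.133, Fisher's exact adjusted p = 0.0451), while hb and Kr had none. The chemoreceptor odds ratio was 0.455 with each peak given to the nearest TSS, 0.211 among genes with a pooled peak at a TSS and 0.0409 in the stronger 5522 peaks. The testis call was lost with TSSs within 250 or 1000 bp, in the stronger 5522 peaks, among genes with a pooled peak and with the nearest TSS (Fisher's exact adjusted p from 0.0568 to 0.581). The segmentation call was lost without replicate 4 (odds ratio 0.134, Fisher's exact adjusted p = 0.051), in the stronger 5522 peaks, with TSSs within 250 bp, among genes with a pooled peak (Fisher's exact adjusted p from 0.0613 to 0.246) and against lists matched on the number of TSSs (permutation, adjusted p = 0.0767). When each IDR peak was given to the protein-coding gene of the nearest TSS at any distance, the direction turned, with an odds ratio of 3.34 (Fisher's exact adjusted p = 0.0142). That measure takes no account of the space around a gene.

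The remaining lists did not pass the threshold in either direction with peaks within 500 bp of a TSS. Both members of the gem and grh family list had promoter peaks (Fisher's exact adjusted p = 0.138). The cuticle, epidermal barrier and wound response list had 4 of 22 (18.2%, Fisher's exact adjusted p = 0.743). These were tyn at 1193, Idgf6 at 1082, rtv at 247 and pio at 230. Neuroblast and neurogenic transcription factor genes had 1 of 21, brat at 576, with none at ase or sc (Fisher's exact adjusted p = 0.098). Hox genes had 2 of 8 (Dfd at 1003 and Antp at 336), and neuron function genes 2 of 16 (elav at 5725 and fne at 875, both RNA-binding proteins of neurons). Glia had 4 of 12 (moody at 2456, Gli at 1573, wrapper at 347 and nrv2 at 290). Muscle had 6 of 22, led by tin at 2746 and sls at 2307, and trachea 4 of 12 (trh at 3020, stumps at 2744, dysf at 1336 and pio at 230). Gut and endoderm had 2 of 13 (bowl at 5464 and fkh at 712), fat body and blood 2 of 20 (Adh at 2087 and vkg at 382) and germline 4 of 15 (piwi at 2898, gcl at 1785, Sxl at 1687 and vas at 920). Heat shock protein genes had 6 of 19, led by Hsp27 at 5638, and the Enhancer of split complex 4 of 11, led by E(spl)m3-HLH at 4217 and E(spl)m7-HLH at 2826, with E(spl)m2-BFM at 2628 and E(spl)mdelta-HLH at 1857. Notch, Wnt, Hedgehog, BMP and EGFR signalling genes had 10 of 31, led by spi (an EGFR ligand) at 4226 and aos at 3369. Polycomb and Trithorax genes had 8 of 21, led by ph-p, E(z) at 4878 and brm at 4479, and passed without replicate 1 (odds ratio 2.93, Fisher's exact adjusted p = 0.0396). For the lists from Hox to Polycomb and Trithorax, adjusted p ran from 0.386 to 1 by Fisher's exact test. With each peak given to the nearest TSS at any distance, 5 of the remaining lists passed as higher: Hox (odds ratio 14), signalling (8.37), gut (6.68), trachea (6.01) and neuroblast genes (3.25), with Fisher's exact adjusted p from 1.05e-06 to 0.0284. For gut (from 0.557) and neuroblast genes (from 0.153) this turned the direction. The nearest-TSS measure takes no account of the space around a gene, and genes with more of it have more chances of a peak. Against random placement of distal peaks, neuroblast genes did not pass (1.20-fold, permutation, adjusted p = 0.31). Hox, signalling, gut and trachea genes passed there, at 1.63-fold to 3-fold. Signalling genes also passed with TSSs within 1000 bp (3.40, Fisher's exact adjusted p = 0.00846), and neuroblast genes passed as lower against lists matched on the number of TSSs (0.164 times their mean, permutation, adjusted p = 0.047).

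**Figure D3:**
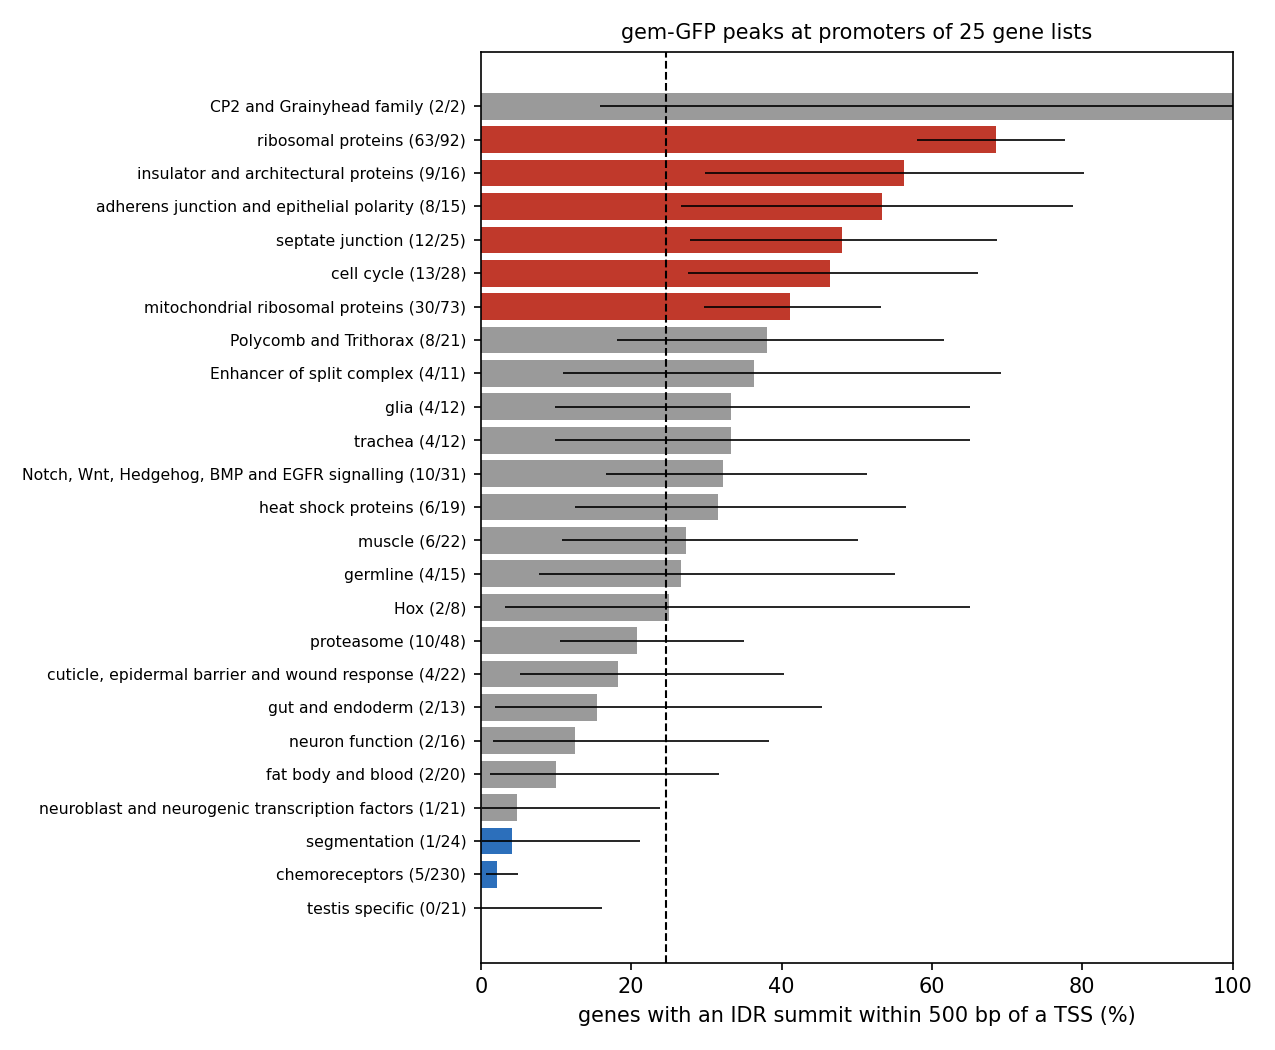
Share of each list's genes (%) with an IDR summit within 500 bp of a TSS, with exact 95% intervals and the numbers of genes in brackets; the dashed line is the share of all protein-coding genes, 24.6%. Red lists were bound more often and blue lists less often than other genes at an adjusted p under 0.05 (Fisher's exact test), grey lists did not pass, and the testis-specific list, which also passed, stands at 0.

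The binding site of the CP2 and Grainyhead family showed no excess at summits that passed the threshold. AACCGGTT with up to 1 mismatch was found within 50 bp of 255 of 11045 summits (2.31%, interval 2.04 to 2.61) and in 2.96% of the windows 500 bp away, an odds ratio of 0.776 (Fisher's exact p = 6.06e-04). The exact AACCGGTT was found at 27 summits (0.244%) and in 0.167% of flanking windows (odds ratio 1.46, Fisher's exact p = 0.145). The direction depended on the background and the replicate: against dinucleotide shuffles of the summit windows the odds ratio was 1.13 (Fisher's exact p = 0.197), and with replicate 4 alone it was 1.04 (Fisher's exact p = 0.535).

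Of 12 further motifs fixed in advance, 2 were more frequent at summits than in the flanks and 8 were less frequent. TATCGATA, the DNA replication-related element bound by Dref at housekeeping promoters, was found at 70 summits (0.634%) and in 0.190% of flanks (odds ratio 3.35, Fisher's exact adjusted p = 4.91e-10). At promoter summits it reached 1.46% against 0.327%, and at distal summits 0.273% against 0.130%. Against shuffles, which keep the composition, the excess was present at promoter summits (odds ratio 5.51, Fisher's exact adjusted p = 9.55e-07) and did not pass at distal summits (1.24, Fisher's exact adjusted p = 0.684). Over all summits the odds ratio was 5.60 without replicate 1, 1.69 with flanks 250 bp away and 2.01 with flanks 1000 bp away. TATAAA was found at 28.5% of summits and 10.3% of flanks, but at 28.4% of the dinucleotide shuffles (Fisher's exact adjusted p = 0.976). The GAGA repeat GAGAGAG (0.507% against 2.5%), the CP2 direct repeat (2.67% against 6.99%) and the PHO site GCCAT (10.9% against 19.5%) were less frequent than in flanks. Against shuffles the GAGA repeat was more frequent (odds ratio 2.01, Fisher's exact adjusted p = 0.00704), and the other 2 of these passed in neither direction. CAGCTG was also less frequent than in flanks (2.14% against 4.71%) and more frequent than in shuffles (odds ratio 2.27, Fisher's exact adjusted p = 8.21e-12). CACGTG was less frequent against both, at 0.380% with 1.32% in flanks and 0.842% in shuffles (Fisher's exact adjusted p = 6.86e-18 and 5.08e-05). The Zelda site (odds ratio 0.801), the initiator (0.856) and CCAAT (0.896) were less frequent than in flanks. The Zelda and CCAAT calls were lost with flanks 250 bp away (0.914 and 0.985, Fisher's exact adjusted p = 0.351 and 0.623) and against shuffles (0.833 and 0.940, Fisher's exact adjusted p = 0.117 for both). Against shuffles the initiator turned direction and lost its call (1.09, Fisher's exact adjusted p = 0.117). The BEAF site (0.969) and Ohler motif 1 (1.04) did not pass. Without replicate 1 both passed as more frequent, BEAF at 1.20 and Ohler motif 1 at 1.48 (Fisher's exact adjusted p = 5.70e-07 and 1.20e-04). BEAF passed as less frequent in the stronger 5522 peaks (0.885) and at distal summits (0.876), and as more frequent at promoter summits (1.16) and within 100 bp (1.07), with Fisher's exact adjusted p = 0.0263, 0.0077, 0.019 and 0.0127. Ohler motif 1 was also more frequent within 100 bp of summits (1.56), against shuffles (1.57) and at promoter summits (1.54), with Fisher's exact adjusted p = 4.98e-10, 0.00653 and 0.0134.

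Summits lay in an AT-rich core, which bears on each of these motif values. Mean GC content within 50 bp was 29.8% (SD 7.99 over 11045 summits), against 43.2% in windows 500 bp away and 42.2% at random positions. It was lower than in its own flanks at 88.3% of summits. The values were 30% at promoter and 29.7% at distal summits, and 29.5% and 30.9% at the strongest 11045 peaks of replicates 1 and 4. In all, 4240 of 32896 8-mers were more frequent at summits than in flanks at an adjusted p under 0.05, among them all 136 made of A and T alone. The first was TTTAAAAA, in 8.24% of summit windows and 1.92% of flanks (exact hypergeometric test, adjusted p = 1.04e-150). Against dinucleotide shuffles, a background added after the data were seen, 358 8-mers passed the threshold, led by AAATATAT (8.31% against 3.72%).

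**Figure D4:**
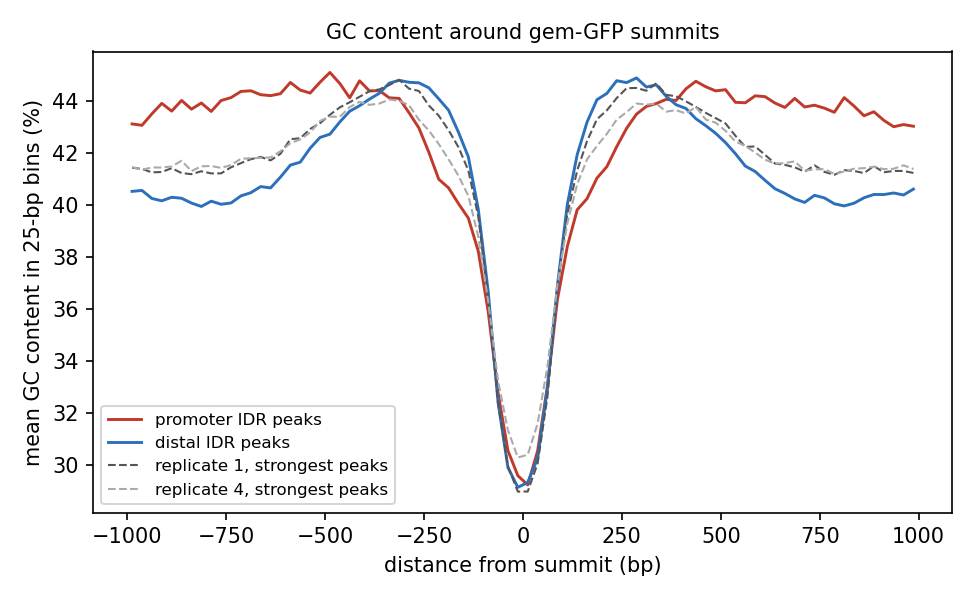
Mean GC content (%) in 25-bp bins by distance from the summit in bp, for 3361 promoter (red) and 7684 distal (blue) IDR peaks and for the 11045 strongest peaks of each replicate (dashed). All 4 curves fall to about 30% at the summit, with a mean within 50 bp of 29.5% to 30.9%.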

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

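Of 366 recomputed values that could change, 254 kept their direction and their side of the threshold, or stayed within the spread set for them. Direction turned in 53, some of them with a call lost or gained. With the direction kept, a call was lost in 42 and gained in 10, and 7 untested values or counts moved. No call changed for replicate overlap (66.1% to 86.5%), the promoter share, promoter against distal signal (0.12 to 0.19 on the log10 scale), the number of bound genes (2426 to 4046), the ribosomal protein list (odds ratio 3.38 to 11.1, and 2.31 times the mean of matched lists) or the chemoreceptor list (odds ratio 0.0409 to 0.455, and 0.106 times that mean). In 2 further settings nothing could move, and their 96 values are not counted: no IDR summit lay within 100 bp of a stronger one, and the IDR list equals the 11045 strongest pooled peaks. Overlap and correlation need both replicates, so neither was left out for them. No paired analysis was possible because there is only 1 group. The cause of a change was not tested unless its construction shows it, and the lack of read depth limits what can be said of weak peaks.

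The Spearman coefficient moved to 0.921 for promoter peaks, 0.851 for distal peaks and 0.862 with matching within 250 bp. The family site had an odds ratio of 1.13 against dinucleotide shuffles, 0.905 with flanks 1000 bp away, 1.46 for the exact site, and 0.716 to 1.04 with either replicate left out. Against shuffles, which take the AT-rich composition into account, the odds ratio turned to 1.21 for the CP2 direct repeat, 2.01 for GAGA, 1.05 for BEAF, 1.09 for the initiator, 2.27 for CAGCTG and 1.02 for PHO. BEAF was 0.885 in the stronger 5522 peaks, where it gained a call, 1.07 within 100 bp and 0.987 to 1.20 with a replicate left out. Ohler motif 1 was 0.769 in the stronger 5522 peaks, 0.841 within 25 bp, 0.840 with flanks 250 bp away and 0.889 with flanks 1000 bp away, and 1.08 to 1.48 with a replicate left out. It was 1.56 within 100 bp and 1.57 against shuffles, where it gained a call. Zelda (0.914 and 0.833) and CCAAT (0.985 and 0.940) lost theirs with flanks 250 bp away and against shuffles, and TATA against shuffles. The replication-related element was 1.69 to 5.60 over all IDR peaks, the stronger 5522 or either replicate alone, and kept its call there. Of the arms, 3R lost its call in the stronger 5522 peaks (0.961). Enriched k-mers numbered 558 for 6-mers, 1695 for 7-mers, 358 against shuffles and 1775 within 100 bp against shuffles, the last 2 added after the data were seen.

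For gene lists the values are odds ratios. In the stronger 5522 peaks they were 1.5 for septate junction, 0 for segmentation and testis, 2.25 for cell cycle and 3.70 for insulator genes, whose calls were lost, and 0.678 for Hox and 0.95 for glia. With TSSs within 250 bp they were 1.11 for septate junction, 3.91 for adherens junction, 0.193 for segmentation, 0 for Hox, trachea, testis and Enhancer of split, 0.405 for glia, 0.445 for muscle, 1.17 for proteasome, 0.660 for signalling and 1.49 for cell cycle. Within 1000 bp they were 2.26 for septate junction, 3.68 for adherens junction, 0.815 for Hox, 1.09 for gut, 0.890 for germline, 0.122 for testis, 3.40 for signalling (now past the threshold), 2.45 for cell cycle and 3.15 for insulator genes. Among genes with a pooled peak at a TSS, a smaller background, they were 1.27 for septate junction, 1.13 for adherens junction, 0.141 for segmentation, 0.282 for Hox, 0.564 for glia and Enhancer of split, 0.281 for muscle, 0.847 for trachea, germline and Polycomb, 0 for testis, 3.20 for mitochondrial ribosomal proteins, 4.25 for proteasome, 0.469 for signalling, 1.84 for cell cycle and 1.27 for insulator genes.

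Against lists matched on the number of TSSs, the ratio to the mean of the lists was 1.53 for septate junction and cell cycle, 1.41 for adherens junction, 0.169 for segmentation, 0.675 for Hox, 0.164 for neuroblast (now past the threshold), 0.866 for glia, 0.702 for muscle, 0.941 for germline, 0.993 for signalling and 2.05 for insulator genes. With each peak given to the nearest TSS, odds ratios were 2.001 for cuticle, 1.85 for septate junction, 3.002 for adherens junction, 3.34 for segmentation, 14 for Hox, 3.25 for neuroblast, 1.56 for neuron function, 6.01 for trachea, 6.68 for gut, 1.33 for fat body, 0.307 for germline, 0.624 for testis, 0.515 for mitochondrial ribosomal proteins, 0.922 for heat shock, 8.37 for signalling, 1.29 for cell cycle and 1.56 for insulator genes; segmentation, Hox, neuroblast, trachea, gut and signalling were past the threshold. With replicate 1 or replicate 4 left out, the range was 2.46 to 2.86 for septate junction, 0.115 to 0.134 for segmentation, 0.885 to 1.85 for Hox, 0.996 to 1.16 for muscle, 0.966 to 1.12 for germline, 1.90 to 2.93 for Polycomb and Trithorax, 2.32 to 3.07 for cell cycle, 5.16 to 7.99 for insulator genes and 5.09 to 11.1 for ribosomal proteins. The septate junction and Polycomb calls changed without replicate 1, and the segmentation and cell cycle calls without replicate 4. The odds ratios with the nearest TSS take no account of the space around each gene.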

Other observations

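The placements of distal peaks, the GC-matched positions, the shuffles for 8-mers, the choice of CACTGA and the tests on promoter location and on chance orientation were chosen after the results were seen. Distal IDR peaks were counted near the genes of each list. Each of the 7684 distal peaks was given to the protein-coding gene of the nearest TSS and compared with 500 random placements outside promoters on the same arm, which takes the space around each gene into account. These placements make no allowance for peaks that cluster around single genes, so the p-values measure departure from random scatter. How much of the sequence around each gene could yield a called peak was not measured. Genes of Notch, Wnt, Hedgehog, BMP and EGFR signalling were nearest to 143 distal peaks against a random mean of 47.7 (3-fold, permutation, adjusted p = 0.0125). Among them, picked for their counts, were fz2 with 24 (random mean 6.61), pnt with 16 (3.09), sty with 13 (2.94) and ptc with 8 (0.76). Gut and endoderm genes were nearest to 41 (2.76-fold, of which 5 each were nearest to Abd-B and lab, also in the Hox list, and 7 to Dr, also in the neuroblast list), Polycomb and Trithorax genes to 22 (2.60-fold, trx alone to 8), glia genes to 25 (2.09-fold, of which 16 were nearest to pnt, which is also in the signalling list), Hox genes to 43 (2.02-fold, Antp alone to 15), septate junction genes to 32 (2.01-fold) and adherens junction genes to 48 (1.87-fold), each with the same adjusted p by permutation, the smallest reached in this family of 25 lists. Segmentation genes were nearest to 55 (1.57-fold, permutation, adjusted p = 0.0166) and trachea genes to 33 (1.63-fold, permutation, adjusted p = 0.0428). Muscle (1.35-fold), neuroblast (1.20-fold), cuticle (1.09-fold) and neuron function genes (0.868-fold) were among the lists that did not pass (permutation, adjusted p from 0.229 to 0.686).

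Other lists were nearest to fewer distal peaks than random placement gave. Ribosomal protein genes were nearest to 15 distal peaks against a random mean of 31 (permutation, adjusted p = 0.0166), mitochondrial ribosomal protein genes to 4 against 22.3 (permutation, adjusted p = 0.0125) and heat shock protein genes to 1 against 6.99 (permutation, adjusted p = 0.0166). Of the mitochondrial random mean, 14.5 came from mRpS5 alone, which had 1 peak, so most of that list's deficit rests on 1 gene. Chemoreceptor genes had 72 against 104 (permutation, adjusted p = 0.0166) and germline genes 9 against 20.5 (permutation, adjusted p = 0.023). Proteasome genes, with 7 against 11, and cell cycle genes, with 16 against 9.11, did not pass (permutation, adjusted p = 0.341 and 0.12). Over all genes, the most distal peaks were nearest to hth, a homeodomain regulator, with 28 (random mean 7.92), followed by CG43658 with 26, fz2 with 24, and tara and CG43245 with 21 each (random means 2.14 and 3.65).

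The AT-rich core of the summits was weighed against 3 technical explanations, and no biological explanation was tested. If whole fragments had been picked for low GC, the deficit against random positions should persist over fragment length. It was 12.3 percentage points within 50 bp of summits, 5.31 within 200 bp and 1.65 within 400 bp, so that 43.2% of it was left at 200 bp, under the 50% set before the test. That window holds the core itself and is longer than the shortest fragments of the labelled 200 to 800 bp, so it cannot decide on these. In the 25-bp bins centred 188 bp to one side and 187 bp to the other, mean GC was 42.7% and 43.1%. Random positions had 42.2%, so the deficit did not reach that far. This argues against GC bias of the longer fragments as the whole cause. A bias of short fragments, or a contribution of long ones, stays open. Repeats did not account for the core: 0.407% of summits lay in annotated transposable elements (random 5.79%), more lay in soft-masked sequence or such elements together (29.9%, random 22.5%), and outside both the deficit was 99.6% of the whole. Promoter location did not account for it either, since distal summits had 89.2% of the promoter deficit.

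Oriented copies of CACTGA flanked a minority of the summits: 1726 of 11045 (15.6%) had an inward copy 30 to 130 bp away and 170 had one on both sides, against 4.17% and 8 of the GC-matched positions. This hexamer begins the 8-mer CACTGAGA, found within 100 bp of 4.36% of summits and in 0.290% of their dinucleotide shuffles. Of 2383 CACTGA sites 30 to 130 bp from IDR summits, 1937 (81.3%, interval 79.7 to 82.8) read toward the summit, where chance orientation gives 50% (exact binomial p = 1.97e-220). The share was 85.4% at distal and 65.6% at promoter summits, and 65.8% at the 18955 pooled peaks outside the IDR list. Positions matched on the GC content of the core had 7.72 sites per 100, against 21.6 at the summits. Of the sites at matched positions, 55.6% read inward (interval 52.2 to 58.9), so composition of the core alone does not give the inward share. Matching covered only 50 bp to either side, so composition over most of the counted range was not matched. CACTGA was chosen after 8-mers around these same summits were seen, so its excess of sites is not a separate test. No protein was tested for this sequence.

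The ribosomal protein genes were weighed against signal at highly transcribed genes in general and against crowded TSSs. Of 113 other housekeeping genes taken to be highly transcribed (translation factors, tubulins and actins, glycolysis, respiratory chain), 41.6% had a promoter peak, fewer than the 68.5% of ribosomal protein genes (odds ratio 3.05, Fisher's exact p = 1.41e-04). The 113 genes were picked by symbol, and their expression in these embryos was not measured. They were themselves above the remaining genes (odds ratio 2.23, Fisher's exact p = 5.71e-05), so high transcription may still account for a part, and how much cannot be told. Random lists matched on the number of TSSs within 1000 bp had a mean of 35.5% and at most 52.2% in 10000 draws, which argues against crowding as the whole cause. Open chromatin was not analysed here and stays untested as an explanation.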
